A study of Danio rerio with 4 samples.

How the data were processed

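The deposited tables hold FPKM values (fragments scaled by transcript length and library size), 1 table per library, for 49610 rows: 35066 with an Ensembl gene identifier and 14544 with an identifier of a merged locus that carries no gene name. No header or label names the unit, which was read from the values, and the values may have been made in another way. Per the labels' protocols, ovaries were snap frozen, total RNA was taken with an RNeasy kit, and libraries made with the NEBNext Ultra kit were read in pairs on an Illumina HiSeq X instrument. The submitters' processing notes name HISAT2, HTSeq 0.6.1 and the genome build GRCz10. Their order and settings, and the annotation, are not given in the sources used here, nor whether strand was used, so overlapping genes cannot be told apart. Per the file headers, the value columns of the DiBP and combined libraries carry short names other than those of their samples, and each table was taken as the sample it is recorded for.

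Gene symbols came from a table of identifiers, in which 26996 of the 35066 Ensembl rows had a match, and are printed as that table gives them. Of 37392 rows above 0 in any library, 3644 share their 4 values exactly with another row, as rows of a merged locus do. These were collapsed, leaving 35253 loci. A gene that shares its value with another named gene cannot be told from it.

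The design fixed before the data were examined was written for counts, with an alternative for normalized values that was used here: log2(FPKM + 1), loci with a mean of at least 1 FPKM over the 4 libraries (13859 loci) and differences of at least 2-fold on that scale. The deposited values were used without further scaling. Each of the 4 groups has 1 library, so no test, p-value or replicate error was computed, and no counting interval can be had from FPKM. The 6 pairs of libraries were compared. The spread that counting alone would give, planned beside the distances between libraries, was not computed, since it needs counts.

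For 29 gene lists fixed beforehand, the median log2 ratio of the measured members was set against 10000 random lists of the same size matched on mean expression in 20 bins. A list was called apart below the 1st or above the 99th percentile. Of 168 list comparisons with a measured member, 29 were called apart, and 3.36 would be by chance if lists behaved like random ones. The percentile describes these libraries and is no p-value, because members are not independent. A symbol was also matched without its final paralog letter where the table lacks it, a choice made after the data were seen, as was the collapsing of rows.

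Genes are named by a rule fixed beforehand. For each comparison with control it takes the 8 highest and 8 lowest ratios among symbols that are not clone names, and up to 3 members with the largest ratio from each list apart and from 10 lists of prior interest. For the other comparisons it takes the 4 highest and 4 lowest. Symbols carried by several rows or sharing a locus with another named gene were skipped. Not every gene the rule takes is printed.

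Relative depth was taken from rows below 0.05 FPKM in both libraries, where the commonest ratio is that of equal read numbers. This rests on 107 to 124 rows per library and gives no absolute depth. Ratios that share the control were set beside 100 draws in which the 4 values of each locus were dealt to the libraries at random. Such draws keep whatever real differences the values hold and remove only their tie to a library.

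The code was tested on simulated data for DBP against control over 13859 loci. All 100 loci changed 4-fold and 0 of 100 changed 1.5-fold were placed beyond 2-fold, as were 0 of 13659 unchanged loci. The simulated library was a copy of the simulated control with slight noise, and only loci at 5 FPKM or more were changed. That noise was far below the spread of the real log2 ratios (SD 0.63 to 0.80). The result checks the code and gives no error rate for the 2-fold rule in these libraries. Of 200 random lists, 4 were called apart. Alternatives were the pseudocount, the filter, 3 scalings (median of ratios, total, and total without the 50 most abundant loci), and how lists were matched and summarised. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.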

Results

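Ovarian mRNA was sequenced from adult female zebrafish of the AB strain, 5 months old, after 30 days of exposure to dibutyl phthalate (DBP), to its branched isomer diisobutyl phthalate (DiBP), or to both compounds, beside an unexposed control. Phthalates of this kind are plasticisers. There were 4 libraries, 1 per group, so no difference given here has a replicate check: each value compares libraries, not conditions, and no p-value or replicate error can be given. Doses were not given in the sources used here. The summed FPKM over all rows was 534379 in the control, 572398 in the DBP library, 598063 in the DiBP library and 512635 in the combined library. Absolute depth is unknown, but the steps between low values put the depth of the DBP, DiBP and combined libraries at 1.05, 0.913 and 1.02 times that of the control. Expression was measured at 13859 loci with a mean of at least 1 FPKM, of which 11022 carried a gene symbol. Ratios are on the log2(FPKM + 1) scale, which understates the difference of low genes.

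Egg-cell transcripts were abundant in the control library, with h1m, the linker histone of the oocyte, at 531 FPKM and the egg-coat gene zpax4 at 963 FPKM. Across loci, which are not independent replicates, the correlation of log2 values ran from 0.912 between DiBP and control to 0.945 between the combined library and control. The SD of the log2 ratio was 0.64 for DBP, 0.80 for DiBP and 0.63 for the combined library against control, and 0.65 for DiBP against DBP. At least 2-fold differences from control were found at 1126 loci in the DBP library, 1981 in the DiBP library and 930 in the combined library. Most of the counts by direction move by more than 1.5 times with a pseudocount of 0.1 or a filter at 5 FPKM.

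The first comparison asks how the ovary exposed to DBP differed from the control. Mitochondrially encoded transcripts stood out: all 10 measured loci were higher in the DBP library, 8 of them by at least 1.5-fold, with a median log2 ratio of 1.58, above all 10000 random lists matched on expression. MT-ND1, a subunit of respiratory complex I, was at 584 FPKM against 89.8 in the control, MT-ND5 at 173 against 35.0 and MT-ND6 at 340 against 77.1. The most abundant loci differed less, with MT-CO2 at 2896 against 1984 and MT-CO1 at 2490 against 1392. The cytosolic ribosomal proteins had a median of 0.29, at the 99.5th percentile, with 8 of 75 loci at least 1.5-fold higher and 0 lower. Genes of 89 other short proteins, a list added after the ribosomal values were seen, were higher as well (median 0.27, 99.99th percentile, 14 higher and 1 lower). RPS28 was at 241 FPKM against 129, RPL26 at 1328 against 756 and RPL10A at 442 against 261. Genes of apoptosis and the p53 response had a median of 0.26, at the 99.8th percentile, with 8 of 37 higher and 2 lower. Among them, the cell-death gene diablob was at 57.5 FPKM against 18.6, pmaip1 at 75.3 against 26.4 and the survivin gene BIRC5 at 87.6 against 49.5.

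Genes of lipid synthesis and storage had a median of -0.35 in the DBP library, at the 0.27th percentile, with 5 of 19 lower and 3 higher. SCD, a fatty acid desaturase, was at 4.70 FPKM against 12.6, whereas the apolipoprotein genes apoeb and apoc1 were higher, at 11.3 against 0.851 and 5.26 against 2.37. Markers of other cell types differed too: of the 4 smooth muscle and vessel loci measured, 3 were higher, with a median of 1.33 at the 99.9th percentile. These were smooth muscle genes: acta2, a smooth muscle actin (2.80 FPKM against 0.833), and loci of TAGLN and MYL9. A locus of the vessel gene CLDN5 was at 0.806 against 1.15. Vessel genes below the filter went both ways, with kdrl at 0.498 against 1.29 and tek at 1.06 against 0.538. The smooth muscle call falls away where at least 5 members are asked for. Just 3 granulosa loci were measured, with a median of 0.82 at the 98.0th percentile in the DBP library and 0.80 at the 96.5th in the DiBP library. The lipid call does not hold without merged loci that hold other genes (1.36th percentile), at a mean of at least 5 FPKM (3.47th) or with the mean of members (15.6th). The cholesterol synthesis list did not stand apart (median -0.07, 5 of 23 lower and 1 higher), although MVD, SC5D and GGPS1 had log2 ratios of -1.54, -1.12 and -1.05. The fatty acid carrier fabp4a was at 25.3 FPKM against 1.55, and ANGPTL4, a lipase inhibitor, at 4.19 against 1.44, within a list of PPAR targets and fatty acid oxidation whose median was -0.05.

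None of the ovarian lists was called apart in the DBP library. The granulosa list leaned higher, with 2 of its 3 measured loci at least 1.5-fold higher and 0 lower. CYP19A1, the aromatase that makes oestrogen, was at 3.65 FPKM against 0.677, and SERPINE2 at 26.8 against 14.7. Most granulosa loci below the filter were also higher, at low values. The steroidogenesis list had a median of 0.02 and the hormone receptor list -0.10, with 13 of its 14 loci within 1.5-fold. The oocyte list had a median of 0.08; h1m was at 1453 FPKM against 531 and figla, a transcription factor of the oocyte, at 41.2 against 17.6. The xenobiotic list (median -0.10) held sult2st2 at 3.25 FPKM against 0.416, and the antioxidant list (median 0.04) held GPX8 at 59.0 against 136 and gpx4a at 12.8 against 30.9.

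Of the named genes with a symbol of their own that the naming rule ranks, which leaves out unnamed loci, clone names and symbols that several rows carry, the DBP library exceeded the control most at SSR1 (40.9 against 0.0297 FPKM), her2 (38.4 against 0.358), the histone gene h2ax1 (169 against 7.81), foxf2b (15.2 against 0.0316), ccdc15 (10.2 against 0.0242) and mir202 (25.8 against 1.58). RFLNB was at 9.11 FPKM and listed at 0 in the control. A locus of MFAP4, a symbol on several rows and picked after its values were seen, was at 38.2 against 0.964. It is a merged locus that also holds another named gene, so the value cannot be credited to MFAP4. Among the ranked genes, the library lay furthest below the control at FBXO42 (10.8 against 249), raver1 (1.84 against 31.2), MIA (0.359 against 7.02), trim35-24 (0.722 against 8.23) and tbc1d10aa (0.442 against 6.01). The heat-shock genes hsp70.3 and hsp70l were at 1.82 against 12.9 and 0.295 against 5.00, and VPS39 was listed at 0 against 4.45 in the control. SSR1 encodes a subunit of the complex through which secreted proteins enter the endoplasmic reticulum, which every cell uses, so its near-zero values in the other 3 libraries cannot be read as absence. Absence cannot be concluded either for other ranked genes at or near 0 in a library, here and in the comparisons below. Examples are foxf2b, ccdc15, NANOS3, crp5, slc22a7b.1 and terb1, each below 0.1 FPKM in a library and at 5 FPKM or more in another. In all, 667 loci were at least 2-fold higher and 459 at least 2-fold lower, or 590 and 527 with total scaling. The ribosomal protein and p53 calls do not hold with the mean of members in place of the median (93.2nd and 98.9th percentiles), nor the former at 5 FPKM (98.7th) or the latter with exact symbols (98.3rd).

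**Figure D1:**
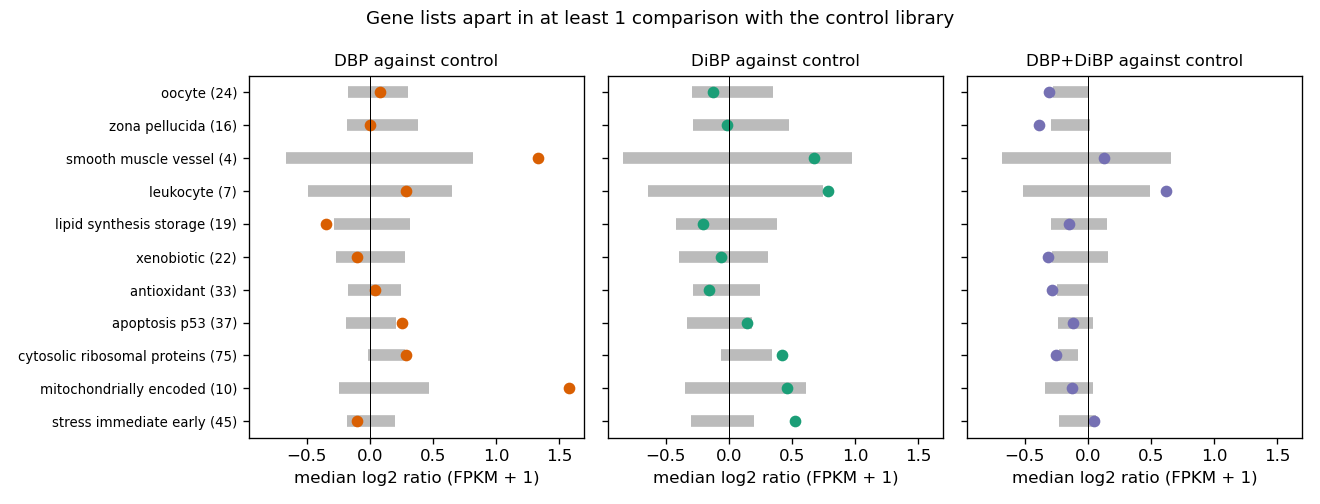
Median log2 ratio (FPKM + 1) of each gene list against control (points, 1 panel per exposed library), with the number of measured loci in brackets and grey bars from the 1st to the 99th percentile of 10000 random lists matched on expression. The mitochondrially encoded list lies at 1.58 in the DBP library and the ribosomal proteins at 0.29, 0.42 and -0.26 in the DBP, DiBP and combined libraries.

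The DiBP library differed from the control at more loci than the other exposed libraries did. Ribosomal protein genes were again higher, with a median of 0.42 at the 99.95th percentile and 29 of 75 loci at least 1.5-fold higher and 0 lower. The other short-protein genes had a median of 0.28 here (99.97th percentile, 17 higher and 2 lower). RPL29 was at 676 FPKM against 144, RPS28 at 316 against 129 and RPS25 at 1978 against 814. Stress and immediate-early genes, a list that also holds heat-shock genes, had a median of 0.52, above all random lists, with 20 of 45 higher and 6 lower. Among them hsp70l was at 30.6 FPKM against 5.00 and ier2b at 6.08 against 0.722, while NR4A1 was lower, at 1.33 against 12.4. This call does not hold at a mean of at least 5 FPKM, where the median was 0.08, or with exact symbols, where it was 0.19 at the 97.5th percentile; with total scaling the median was 0.31, still above all random lists.

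The leukocyte list had a median of 0.78 in the DiBP library, at the 99.2nd percentile, over 7 loci, with 4 at least 1.5-fold higher and 1 lower. Of its members, cd74a, which serves antigen presentation, was at 2.74 FPKM against 1.04 and lyz at 1.09 against 0.922. The merged MFAP4 locus, which also holds another named gene, was at 23.1 against 0.964. The list's percentile was 90.4 without merged loci that hold other genes, 95.5 with a pseudocount of 0.1, 98.5 with the mean of members and 98.96 with total scaling, so the call rests on the setting. At 5 FPKM, 2 loci are left, the merged MFAP4 locus among them, and the median was more than 2 times as high (99.6th percentile). In the DBP library the leukocyte list had a median of 0.28 at the 84.6th percentile, with 3 of 7 loci higher and 0 lower. This does not show fewer leukocyte transcripts there, since loci below the filter, picked after their values were seen, went several ways. In the control, DBP, DiBP and combined libraries ptprc was at 0.0240, 0.481, 0.296 and 0.0342 FPKM. Likewise laptm5 was at 0.144, 0.851, 0.643 and 0.225, but mhc2dab at 0.120, 0, 0.931 and 0.262. The mitochondrially encoded list had a median of 0.46 in the DiBP library, at the 93.7th percentile, and did not stand apart. Of its 10 loci 4 were at least 1.5-fold higher and 0 lower. The p53 list had a median of 0.15 at the 97.6th percentile, with pmaip1 at 66.0 FPKM against 26.4, diablob at 41.0 against 18.6 and RRM2B at 1.46 against 4.99.

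None of the ovarian and metabolic lists was called apart in the DiBP library. Of the 3 measured granulosa loci 2 were at least 1.5-fold higher and 0 lower. CYP19A1 was at 4.18 FPKM against 0.677 and SERPINE2 at 26.4 against 14.7, while HSD17B4 was at 5.83 against 10.3 and CBR1 at 4.78 against 8.83. The steroidogenesis list had a median of -0.12, with 3 of 21 loci higher and 6 lower, and all 14 hormone receptor loci were within 1.5-fold. In the oocyte list (median -0.12), h1m was at 1890 FPKM against 531, BTG4 at 159 against 111, and NANOS3, a germ-cell RNA regulator, was listed at 0 against 10.6. Among cholesterol genes (median -0.14), FDFT1 was at 3.26 FPKM against 10.4, the sterol regulator srebf2 at 11.6 against 26.1 and LSS at 2.90 against 1.33. The PPAR and fatty acid oxidation list (median -0.15, 9 of 38 lower and 4 higher) held ANGPTL4 at 5.90 against 1.44, fabp4a at 5.65 against 1.55 and ACSL5 at 4.31 against 11.8. In the xenobiotic list (median -0.06), cyp2y3 was at 0.202 against 2.04 and cyp1d1 at 0.524 against 2.53. In the antioxidant list (median -0.15), GPX8 was at 37.7 against 136 and gpx1b at 36.5 against 14.1.

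Among the ranked genes, the DiBP library exceeded the control most at her2 (72.5 against 0.358 FPKM), foxf2b (34.1 against 0.0316), the epithelial adhesion gene epcam (1147 against 86.8), ccl38.6 (9.49 against 0.0510), znfl2a (57.3 against 5.76), ccdc15 (6.95 against 0.0242) and CNN2 (8.31 against 0.320). RFLNB was at 14.1 FPKM and listed at 0 in the control. Their lowest ratios were at dap1b (7.08 against 261), taco1 (1.35 against 24.3), ftr67 (1.92 against 29.8), GATB (6.51 against 78.0), pik3ap1 (0.625 against 16.0) and ADCY8 (0.594 against 15.5), and crp5 was listed at 0 against 13.0. At least 2-fold differences were seen at 1005 loci higher and 976 lower, or 50.7% higher; that share was 41.3% with total scaling and 57.4% with median-of-ratios scaling, so the balance depends on the scaling.

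In the library exposed to both compounds, several lists lay below the control. Egg-coat genes had a median of -0.39, at the 0.01st percentile, and oocyte genes -0.31, at the 0.15th percentile, against -0.08 for all loci. Most members differed little: 15 of 16 egg-coat loci and 21 of 24 oocyte loci were within 1.5-fold. The egg-coat gene zpd was at 17.4 FPKM against 35.8, zpax4 at 658 against 963 and zp3c at 284 against 407. Of the oocyte genes, DAZL was at 13.2 against 25.2, CCNB1 at 171 against 256, and NANOS3 was listed at 0 against 10.6. The ribosomal proteins, higher in both single-exposure libraries, had a median of -0.26 here, at the 0.14th percentile. Most were within 1.5-fold (71 of 75), with 4 lower and 0 higher, among them RPL12 at 484 FPKM against 817, RPL22 at 352 against 581 and RPL9 at 155 against 250. With median-of-ratios scaling that median was -0.17. Genes of very long proteins, also a list added later, were higher (median 0.29, above all random lists, 6 of 62 higher and 0 lower), while the other short-protein genes had a median of -0.14 at the 34.04th percentile.

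The antioxidant list had a median of -0.29 (0.19th percentile, 7 of 33 lower and 1 higher), with GPX8 at 31.2 FPKM against 136 and KEAP1, the sensor of oxidative stress, at 8.65 against 17.4. The xenobiotic list had a median of -0.32 (0.48th percentile, 7 of 22 lower and 2 higher), with mgst3b at 33.5 against 61.0, cyp2y3 at 0.658 against 2.04 and sult2st2 higher, at 1.93 against 0.416. The leukocyte list had a median of 0.62 at the 99.7th percentile, with lyz at 2.64 FPKM against 0.922 and cd74a at 0.485 against 1.04. Of its 7 loci 4 were at least 1.5-fold higher and 1 lower. Below the filter, cd74b was at 0.481 against 0.533 and a SPI1 locus at 0.549 against 0.538, close to the control. With the mean of members in place of the median, 0 of these 6 lists stands apart. At 5 FPKM the xenobiotic, leukocyte and ribosomal lists do not, nor do the antioxidant and leukocyte lists without merged loci, or the antioxidant list with exact symbols (1.71st percentile).

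Aromatase was close to the control in the combined library, with CYP19A1 at 0.837 FPKM against 0.677, while HSD17B4 was at 3.71 against 10.3, STARD3 at 13.5 against 23.6 and cyp17a2 at 1.72 against 3.27. The steroidogenesis list had a median of -0.20, at the 10.2nd percentile, and the hormone receptor list -0.10, with PGRMC1 at 41.2 against 56.2. The cholesterol list had a median of -0.16, with FDFT1 at 4.59 FPKM against 10.4 and insig1 at 13.7 FPKM (log2 ratio 0.55). In the PPAR list (median -0.11), fabp4a was at 8.79 against 1.55 and hadhaa at 34.8 against 18.4. The p53 list had a median of -0.11, with FADD at 4.42 against 8.59 and bcl2a at 2.79 against 5.07. The mitochondrially encoded list had a median of -0.13 at the 61.8th percentile. Of its 10 loci 3 were at least 1.5-fold higher (MT-ND1, MT-ND5 and MT-ND6) and 2 lower.

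Among the ranked genes, the combined library exceeded the control most at h2ax1 (133 against 7.81 FPKM), TRIM9 (18.1 against 0.665), ccdc15 (10.3 against 0.0242), hist2h2l (26.9 against 2.69), nub1 (8.26 against 0.283) and hsp70l (41.4 against 5.00). slc22a7b.1, at 35.2 FPKM, and st3gal7, at 10.3, were listed at 0 in the control. Of these genes, it lay furthest below at FBXO42 (2.70 against 249), terb1 (0.0591 against 12.2), ADCY8 (0.578 against 15.5), lnc.85 (0.119 against 8.67) and MIA (0.146 against 7.02), and crp5 and GBA3 were listed at 0 against 13.0 and 7.21. At least 2-fold differences were seen at 482 loci higher and 448 lower, or 51.8% higher; that share was 58.3% with median-of-ratios scaling and 60.1% with total scaling without the 50 most abundant loci.

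**Figure D2:**
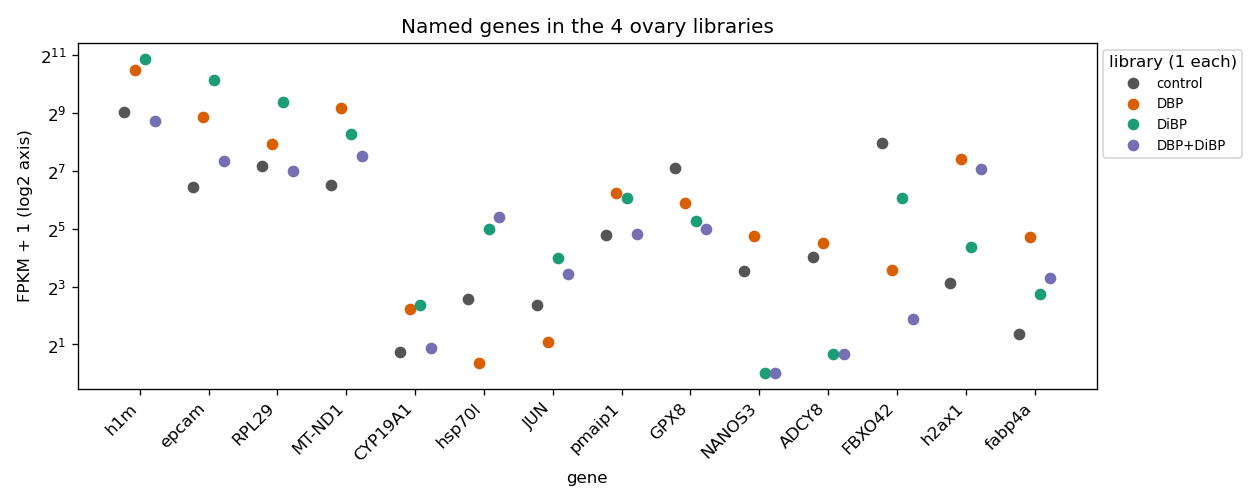
FPKM + 1 on a log2 axis (vertical) for 14 genes (horizontal) in the 4 libraries, 1 point per library, the genes having been picked for the plot after their values were seen. NANOS3 is listed at 0 in the DiBP and combined libraries, from which absence cannot be concluded. h1m stands at 1453 and 1890 FPKM in the single-exposure libraries against 531 and 427 in the control and combined libraries.

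DBP and DiBP are isomers that differ in the branching of the butyl chains, and the libraries exposed to each were set side by side at the same 30 days. Whether the doses matched is not known, and with 1 library each the difference has no test and no interval. Mitochondrially encoded transcripts were lower in the DiBP library, with a median of -0.92 below all random lists and 9 of 10 loci at least 1.5-fold lower. Stress and immediate-early genes were higher, with a median of 0.32 above all random lists and 15 of 45 higher against 1 lower. That median was 0.14 at a mean of at least 5 FPKM (99.7th percentile), and the mean of members was 0.63. There hsp70l was at 30.6 FPKM in the DiBP library against 0.295 in the DBP library, hsp70.3 at 28.2 against 1.82 and JUN, a transcription factor subunit, at 14.9 against 1.13. Ribosomal proteins were higher by a median of 0.23, above all random lists, with 8 of 75 higher and 0 lower, while the other short-protein genes differed little (89.1st percentile, 3 of 89 higher and 4 lower). Cell cycle genes were lower by a median of -0.23 (0.04th percentile), although 51 of 55 were within 1.5-fold and the mean of members lay at the 1.94th percentile. With median-of-ratios scaling the cell cycle median was -0.13. The theca and stroma list had a median of -0.80 over 6 loci (0.12th percentile, or 4.26th with exact symbols). Of these, 3 were at least 1.5-fold lower (thy1, a POSTN locus and a CYP11A1 locus) and 3 were within 1.5-fold.

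Further single genes set the isomers' libraries apart. raver1 was at 34.4 FPKM in the DiBP library against 1.84 in the DBP library. Of the ranked genes, the DiBP library was lowest relative to DBP at dap1b (7.08 against 496), SSR1 (0.0992 against 40.9), ftr67 (1.92 against 56.2) and NANOS3, listed at 0 against 25.9. At least 2-fold differences were found at 551 loci higher and 587 lower in the DiBP library, or 48.4% higher, and 54.4% with median-of-ratios scaling. Aromatase did not separate them, with CYP19A1 at 4.18 FPKM in the DiBP library and 3.65 in the DBP library.

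Against the DBP library, the combined library was lower at all 10 mitochondrially encoded loci (median -1.12, below all random lists), at 29 of 75 ribosomal protein loci by at least 1.5-fold (median -0.48) and in the p53 list (median -0.40, 14 of 37 lower and 2 higher). Antioxidant genes (median -0.44), xenobiotic genes (-0.34) and the smooth muscle and vessel list (-1.20) also had lower medians, and stress genes a slightly higher one (0.09). Of the 4 smooth muscle and vessel loci 3 were lower, while CLDN5 was at 1.12 FPKM against 0.806. The other short-protein genes were lower too (median -0.40, below all random lists, 24 of 89 lower and 2 higher) and the very long ones higher (median 0.30, above all random lists, 9 of 62 higher and 0 lower). Of these calls, the p53, ribosomal and mitochondrially encoded calls hold under all 9 alternatives. The antioxidant and xenobiotic calls do not hold with exact symbols (8.11th and 4.92nd percentiles) or the mean of members (6.37th and 4.7th), the antioxidant call without merged loci (11.3rd), or the xenobiotic call with total scaling (median -0.19, 3.21st). The smooth muscle call falls away where at least 5 members are asked for, and the stress call with 5 of the alternatives. The stress median was 0.17 with median-of-ratios or total scaling and 0.05 at 5 FPKM, and the mean of members was 0.41 (99.98th percentile), so its size is not settled. Among the ranked genes it exceeded the DBP library most at hsp70l (41.4 against 0.295 FPKM), slc22a7b.1 (35.2 against 0.181), raver1 (31.2 against 1.84) and st3gal7 (10.3 against 0.0428). It was lowest at SSR1 (0.0699 against 40.9) and ADCY8 (0.578 against 21.9), with NANOS3 and GBA3 listed at 0 against 25.9 and 17.6. There were 383 loci at least 2-fold higher and 629 lower, or 37.8% higher; that share was 53.4% with total scaling without the 50 most abundant loci.

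Against the DiBP library, the combined library was lower at 49 of 75 ribosomal protein loci by at least 1.5-fold (median -0.69, below all random lists) and in the p53 list (median -0.33, 8 of 37 lower and 3 higher). The ribosomal genes were not alone: the other short-protein genes were lower (median -0.41, below all random lists, 27 of 89 lower and 2 higher) and the very long ones higher (median 0.34, above all random lists, 13 of 62 higher and 0 lower). The p53 call does not hold with exact symbols (1.1st percentile). The cell cycle list had a median of 0.10 at the 99.5th percentile, or the 83.0th with the mean of members and the 90.6th among unmatched lists. With total scaling, which moves all loci by a median from -0.01 to 0.12, the p53 median was -0.17 and the cell cycle median 0.25. dap1b was at 146 FPKM against 7.08 and the peptidase gene ENPEP at 14.5 against 0.182, and slc22a7b.1 and st3gal7 were listed at 0 in the DiBP library. foxf2b was at 0.124 against 34.1, FBXO42 at 2.70 against 66.7, her2 at 5.49 against 72.5 and the meiosis gene terb1 at 0.0591 against 10.8. There were 611 loci at least 2-fold higher and 827 lower, or 42.5% higher; that share was 56.4% with total scaling and 59.6% without the 50 most abundant loci.

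The design also asks whether the combined library showed the sum of the single exposures. Over 2724 loci at least 2-fold from control in any exposed library, the slope of the combined log2 ratio on the sum of the single ratios was 0.293. When the 4 values of each locus were dealt to the libraries at random, the mean slope was 0.35 (0.318 to 0.382), because the control enters every ratio. The observed slope lay below all of these draws, in which the libraries are alike by construction. The median of the combined ratio minus the sum was -0.33, against -0.01 (-0.10 to 0.10) after dealing at random. This median shifts with library scaling, which the draws even out. Total scaling divides the DBP, DiBP and combined values by 1.06, 1.09 and 0.976, which would raise it. The median under other scalings was not computed. Of 355 loci at least 2-fold higher in both single-exposure libraries, 155 were also 2-fold higher in the combined library and 199 were within 2-fold of control. Dealt at random, the values gave 236 such loci on average, with 120 (100 to 142) and 113 (91 to 139). Of 271 loci lower in both, 94 were also lower in the combined library and 160 were within 2-fold. At random these were 230, 119 (95 to 139) and 106 (83 to 134) on average. The draws start from fewer loci, so these counts are not like for like. Without the control, 1138 loci differed at least 2-fold between the isomers' libraries, and at 64.7% of them the combined library lay between both. Values dealt at random gave a mean of 64.5% (61.4 to 69.2%), so this share says nothing of the exposures.

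The ratios of DBP and DiBP to the control correlated at 0.610 across loci, against a mean of 0.50 with values dealt at random, and their covariance was 0.316 against 0.238. For DBP and the combined library these were 0.476 against 0.499 and 0.193 against 0.237, and for DiBP and the combined library 0.506 against 0.502 and 0.256 against 0.239. DBP and DiBP shared 355 higher and 271 lower loci, where values dealt at random shared 236 and 230 and independent lists would share 48.4 and 32.3. DBP and the combined library shared 239 and 129, against 234 and 230 at random and 23.2 and 14.8 for independent lists. DiBP and the combined library shared 280 and 215, against 235 and 230 at random and 35.0 and 31.5 for independent lists. Of these 6 overlaps, those of DBP with DiBP and that of higher loci for DiBP and the combined library lay above the range of the 100 random draws, and that of lower loci for DBP and the combined library lay below it. The draws give all pairs lists of similar length, whereas the real lists ran from 448 loci (combined, lower) to 1005 (DiBP, higher). A place outside the range may therefore reflect list length, and by itself shows neither more nor less sharing. Values dealt at random, which also share the control, exceeded independent lists in all 6 overlaps. With 1 control library the controls cannot be split, so part or most of the excess over independent lists may come from the shared control.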

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

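The filter at 5 FPKM, the restriction to named loci, the omission of loci near 0, and the rules for merged loci, exact symbols and list size were chosen after seeing the data, the last 3 after list medians had been seen. No paired analysis was possible because each group has 1 library and all carry the number 1; leaving out a replicate was not possible either. The planned count-based choices (the count normalization, count filters, counting interval and prior count) were not run, since the values are FPKM. With no counts, what depth limits cannot be stated beyond the relative depths.

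Counts beyond 2-fold stayed within 1.5 times of the reported ones under all 3 scalings, with no filter, with all rows kept and without loci near 0 in a library. With a pseudocount of 0.1, which weighs low genes more, the higher and lower counts became 1094 and 789 for DBP against control, 860 and 833 for the combined library against control, 681 and 1052 for it against DBP, 1044 and 1279 for it against DiBP, and 847 and 960 for DiBP against DBP, and the lower count for DiBP against control 1498. The SDs then became 0.97, 0.99 and 0.99 for DBP against control, combined against control and DiBP against DBP. At a mean of at least 5 FPKM, with fewer loci (8427), the counts in the order DBP, DiBP and combined against control, combined against DBP, combined against DiBP, and DiBP against DBP were 264 and 239, 430 and 529, 180 and 189, 154 and 278, 317 and 394, and 205 and 254. Among named loci (11022) they were, in that order, 375 and 247, 524 and 648, 232 and 264, 166 and 387, 355 and 456, and 235 and 372.

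Scaling moved the median ratio of all loci from -0.06 to -0.16 (total) for DiBP against control and from -0.01 to 0.12 (total) or 0.15 (without the top 50) for the combined library against DiBP, and from -0.09 to 0.07 (without the top 50) for it against DBP. The number of lists apart for the combined library against control went from 6 to 0 with the mean of members and to 3 at 5 FPKM, and against DBP from 7 to 4 with exact symbols. Of the 29 list calls, the mean of members ended 14, exact symbols 8, the 5 FPKM filter 7, leaving out merged loci 6, total scaling 3, a minimum of 5 members 2, and the other 3 settings 1 each. No list call changed sign, but medians of small lists moved by more than 1.5 times. At 5 FPKM smooth muscle, with 1 locus left, stood at 2.41 for DBP against control and -2.15 for the combined library against DBP, leukocytes at 1.23 for the combined library against control (over 2 loci), and theca and stroma at -1.21 for DiBP against DBP. With a pseudocount of 0.1 the smooth muscle medians were 2.11 and -1.92, and that of leukocytes in the combined library 1.13. With exact symbols theca and stroma stood at -0.38. Calls that held under all 9 settings were the mitochondrially encoded list in its 3 comparisons; ribosomal proteins in DiBP against control, DiBP against DBP and the combined library against each single exposure; the p53 list in the combined library against DBP; and stress genes in DiBP against DBP.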

Other observations

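The tests reported here were all chosen after the result they bear on was seen; the lists of short and long proteins were written after the ribosomal values were seen, though before their own. Vitellogenins, the yolk precursors made in the liver, were near 0 except in the combined library, where the locus shared by vtg1, vtg4, vtg5, vtg6 and vtg7 was at 1.42 FPKM against 0.000727 in the control and vtg2 at 1.01 while listed at 0 in the control. Among immediate-early genes outside the naming rule, picked after their values were seen, egr1 was at 2.23 FPKM in the DiBP library against 0.231 in the control and 0.188 in the DBP library, and FOSB at 2.83 against 0.235 and 0.111, both below the filter on the mean. The adhesion gene thy1, a member of the theca and stroma list and likewise picked afterwards, was at 324 FPKM in the control, 191 in the DBP library, 36.6 in the DiBP library and 113 in the combined library.

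Each compound's difference can be taken with no library in common, once without and once with the other compound, a comparison added after seeing the data. For DBP the 2 ratios correlated at -0.26 across loci, and for DiBP at -0.11, where values dealt at random gave about 0. For DBP 57 loci were 2-fold higher and 38 lower both times and 258 went opposite ways, against 94.5, 94.4 and 191 at random. For DiBP these were 117, 94 and 239, against 94.4, 94.9 and 190. Among the loci that did go together, h2ax1, hist2h2l (2.69, 27.3, 4.86 and 26.9 FPKM in the control, DBP, DiBP and combined libraries) and FKBP6 (1.81, 20.3, 4.78 and 17.3) were higher, and TMEM167A (50.3, 18.5, 57.6 and 13.0) lower, with DBP. With DiBP, kctd12b (0.0956, 0.259, 4.72 and 2.89) was higher and BHLHE23 (3.52, 4.50, 0.0301 and 0.0498) lower. These genes were picked after their values were seen. The DiBP and combined libraries are also those whose value columns carry short names other than their samples' own. What those names mark is not known, so a difference between the files cannot be told apart from DiBP. Aromatase and h1m were higher in both single exposures alone, as was foxq1b (7.25, 28.7, 22.8 and 9.11), while SMARCC1 (38.3, 14.9, 13.9 and 36.7) and STT3B (55.6, 22.9, 20.7 and 39.1) were lower in both alone.

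Ribosomal protein mRNAs were higher in the DBP and DiBP libraries and lower in the combined library. These mRNAs are short, and a trend with transcript length may contribute: genes of other short proteins, a list written before it was tested, also lay high, at the 99.99th and 99.97th percentiles (medians 0.27 and 0.28 over 89 loci). Genes of very long proteins were not low there (59.19th and 78.2nd percentiles over 62 of 84 genes), which goes against a trend over the whole range of lengths, and between DiBP and DBP ribosomal mRNAs were higher (median 0.23) with the other short ones little moved (3 of 89 higher and 4 lower), which a trend with length alone would not give. In the combined library, however, the long ones were high (medians 0.29, 0.30 and 0.34 against control, DBP and DiBP, above all random lists), and the short ones low against DBP and DiBP (-0.40 and -0.41, below all random lists). A response to either compound would be expected in the combined library too, whose median was -0.26, but 1 library excludes nothing: both explanations stay open for the differences from control, and without replicates exposure cannot be told apart from differences between the fish or libraries.

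Of 9541 loci at 5 FPKM or more in a library, 191 were below 0.1 FPKM in another, 10.3% of those without a symbol and 0.589% of those with one. Values moved to another locus by the authors' processing are a candidate explanation, since SSR1, which every cell uses, is among them; but of 166 other loci of such genes 0 showed it, where the rate of named loci predicts 0.978, too few to decide. The control was the odd library in 37.4% of the 131 loci with 1 odd library (exact 95% interval 29.1 to 46.3%, covering the count of loci only, which are not independent), above an even 25%. With 1 control library, an effect of exposure and a control fish or library that differs cannot be told apart.

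A block of 5 unnamed loci with neighbouring numbers summed to 33977 FPKM in the combined library, 7.63% of its total over loci, against 2841 in the control, 701 in the DBP library and 623 in the DiBP library. Ribosomal RNA carried over could account for it, but the rows named 5.8S ribosomal RNA had a log2 ratio of -0.44 between the combined library and the control. Only 1 of these 3 rows is above 1 FPKM in the control, so the test does not decide. Rescaled to the total without the block, the median ratio of all loci in the combined library against control was 0.04. It was -0.05 with total scaling that keeps the block, and -0.08 without scaling. No biological explanation was tested.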
